A study of Homo sapiens with 18 samples.

How the data were processed

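Total RNA of 18 samples of sorted human regulatory T cells was measured, 9 kept in medium without IL-2 and 9 in medium with IL-2 at 100 u/ml, each for 24 h. Per the labels' protocols, 100 to 200 ng of RNA was amplified in 1 linear round and labelled with biotin (NuGEN V2), and Affymetrix Human Gene ST 1.0 arrays were hybridised. The deposited values are log2 intensities of 33268 transcript clusters per array, and per the submitters' processing notes they were made with RMA, which corrects background, normalizes quantiles and summarizes probes. The version, settings and software of RMA are not given in the sources used here. All 18 columns were used. Their medians ran from 6.56 to 6.73 and their values from 1.79 to 14.2, with no centring of genes, and no detection call per probe set was used here. Arrays have no sequencing depth, so the number of arrays limits the precision.

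Transcript clusters were named through GEO's platform annotation, whose symbols were checked through Entrez identifiers against NCBI RefSeq genes: 19458 had 1 gene symbol, 1750 several and 12060 none, 19427 of the first matched by identifier, and 0 symbols needed an update. A transcript cluster with several symbols or none names no gene here. XIST, TSIX and Y-linked genes (24 transcript clusters) were left out of every table. Where a gene had more than 1 transcript cluster (766 genes) the one with the highest mean over all 18 samples was kept, which left 18394 genes. No filter on dim genes was applied.

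Groups were taken from the labels. The labels give each sample a number from 1 to 9 that both groups share, and they do not say that same-numbered samples share a donor. Nothing in the labels says that the samples came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical in part. No 2 columns were identical, and correlations within a group ran from 0.975 to 0.994. Whether the numbers pair the samples was decided from correlations, not from calls: the deviations from the group means correlated between same-numbered samples by 0.398 to 0.733, each over 0.1, and 8 of 9 media and 8 of 9 IL-2 samples correlated best with their own number, number 1 being the exception (0.398 with its own number, 0.400 and 0.460 with another). The pairing is thus taken from the data and the shared numbers, and values with the number as a block are printed where they change a call.

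The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, IL-2 minus media, 1 mean per group, no block), with a two-sided moderated test and Benjamini-Hochberg adjustment over all 18394 genes. A gene was called at an adjusted p under 0.05, and the fold limit was 1.5. The 34 gene lists and 10 cell type marker lists were tested together with camera of the same package (preset correlation 0.01, adjusted over all 44 lists). With a correlation estimated per list, 8 of the 24 called lists kept their call: STAT5-inducible genes, feedback inhibitors, ribosome biogenesis, amino acid transport and synthesis, purine and pyrimidine synthesis, cytosolic chaperones, anti-apoptotic genes and hypoxia-inducible genes. With the block as well, 2 lists passed. The lists were written from general knowledge, and none of them was chosen on these samples. The groups, the tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined.

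The genes named are the 10 with the largest rise and the 10 with the largest fall among called genes (without open reading frame, pseudogene, small RNA and antigen receptor segment names), 20 genes fixed in advance, and from each gene list up to 4 called members with the largest difference. Of the 20 fixed genes, 1 is not reported here. Genes named for another reason are said to have been chosen after their values were seen.

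Alternatives fixed in advance were the replicate number as a block and as a random block (duplicateCorrelation, statmod 1.5.0), a second quantile normalization, centring each array on its median, leaving out the dimmest 40% of genes, the mean of all transcript clusters of a gene, every transcript cluster as its own feature, eBayes with trend and robust settings, array weights, exact rank-sum tests, an adjusted p under 0.01, an estimated correlation in camera, and leaving out each replicate number in turn. Added after the data were seen were cyclic loess, cyclic loess with the block, and leaving out replicates 1 and 8. The scripts were tested on simulated data for the comparison of IL-2 with media over 18394 genes, in which 100 genes changed 1.5-fold and 100 changed 2-fold: limma without the block recovered 89% and 99% of them with 0 unchanged genes called, limma with the block 94% and 100% with 7 unchanged genes called, and the rank-sum test 77% and 96% with 0. camera called the 1 raised list and 0 of 40 unchanged lists, but the simulated genes varied independently of each other. The real lists had estimated correlations of up to 0.527 without the block. The simulation thus cannot show how often camera calls an unchanged list of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.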

Results

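Regulatory T cells are the FOXP3-expressing CD4 T cells that restrain immune responses, and they depend on interleukin-2 (IL-2), a growth factor made mostly by other T cells. The cells measured here came from human peripheral blood and were sorted as CD4 positive with low CD127 and high CD25, where CD127 is the interleukin-7 receptor encoded by IL7R and CD25 the alpha chain of the IL-2 receptor encoded by IL2RA. They were kept in culture for 24 h, in 9 samples with IL-2 at 100 u/ml and in 9 samples in medium alone. Total RNA was hybridised to 1 array per sample, and the medians of the 18 arrays lay between 6.56 and 6.73 on the log2 scale. The series asks which transcripts in these cells depend on IL-2. The number of arrays limits the precision of every value.

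More genes were higher than lower with IL-2. Of 18394 genes tested with limma, 813 were higher and 235 lower with IL-2, 249 and 41 of them by at least 1.5-fold. The largest rises were in CISH, an inhibitor of cytokine signalling (8.33-fold, log2 difference 3.06 ± 0.17 SE, adjusted p = 2.09e-10), in PMCH, a neuropeptide precursor (7.03-fold), in the adhesion receptor CEACAM1 (6.81-fold) and in SOCS2, another inhibitor of cytokine signalling (4.98-fold). The media levels of PMCH (3.93 ± 0.15) and CEACAM1 (6.19 ± 0.26) lay below 6.27, the 95th percentile of the mean levels of 361 olfactory receptor genes that serve as a guide to background, so their folds and ranks are uncertain. The largest fall was in NCAPH, a subunit of the condensin complex that compacts chromosomes (2.46-fold lower, log2 difference -1.30 ± 0.17 SE, adjusted p = 4.05e-05). With the replicate number as a block in the model, which compares same-numbered samples with each other, 2464 genes were higher and 1568 lower. By at least 1.5-fold they were 269 and 56. All 1048 genes called without the block passed with the same sign. The block and another scaling of the arrays each moved the balance. Higher genes made up 77.6% of the calls as deposited and 61.1% with the block. They made up 61.1% after a second quantile normalization (639 higher and 407 lower) and 65.7% after cyclic loess (703 higher and 367 lower). The count of lower genes was 153, 122 and 152 without replicate 4, 7 and 9 in turn. The 41 genes at least 1.5-fold lower became 24 with the exact rank-sum test, 25 at an adjusted p under 0.01 and 69 with the block after cyclic loess.

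**Figure D1:**
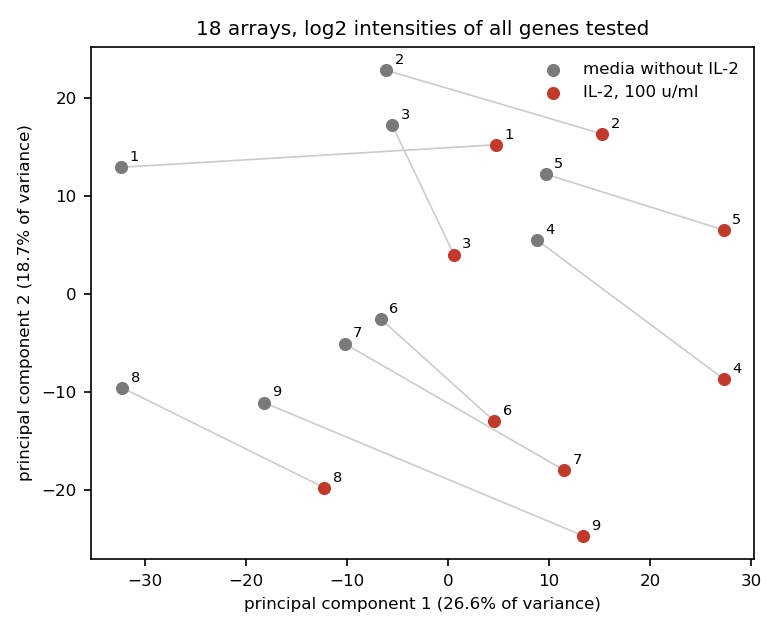
Principal components 1 and 2 of the 18 arrays, computed from the log2 intensities of all genes tested, with the percent of variance on each axis. Each point is 1 sample with its replicate number, coloured by group, grey lines join same-numbered samples, and in all 9 pairs the IL-2 sample lies to the right of its media sample on component 1 (26.6% of the variance).

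In the principal components of the arrays each IL-2 sample lay above the media sample of its number on component 1. Component 2 held 18.7% of the variance. Media samples 1 and 8 stood farthest out on component 1, at -32.3 and -32.2. Without replicates 1 and 8, an alternative added after the data were seen, 578 genes were higher and 182 lower. Each gene named from here on that passed the test moved its way in all 9 same-numbered pairs unless another number is given. Values are log2 differences, IL-2 minus media, ± SE with 9 samples per group, and "with the block" marks the fit that holds the replicate number. A gene that "rose" or "fell" was higher or lower with IL-2 than in medium alone. All samples were taken after 24 h and none before culture, so a gain with IL-2 cannot be told from a loss without it. For gene lists, camera called 22 up and 2 down. In 100 splits of the samples that part all 9 pairs the others had a median of 11 lists in their larger direction, and 5 splits, the real one included, had 22 or more. With the block 3 splits had as many as its 24 lists up, and among 100 splits of any kind 4 had 22 or more. A call of a list is thus weaker evidence than its p reads. For the 2 lists down chance is not excluded in any of these fits. As many lists in the larger direction came up in 89 splits that part all pairs, 88 with the block and 92 of any kind.

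Genes of the IL-2 signalling pathway that STAT5 is known to induce rose together. Of 30 measured STAT5-inducible genes, 18 rose and 12 did not pass, and 22 rose when adjusted over the list alone (median log2 difference 0.70, camera, adjusted p = 1.04e-27). IL2RA went from 10.34 ± 0.39 in media to 11.95 ± 0.38 with IL-2 (mean ± SD, n = 9, 3.06-fold, adjusted p = 8.72e-07). CISH went from 7.35 ± 0.14 to 10.41 ± 0.56 and SOCS2 from 6.43 ± 0.31 to 8.74 ± 0.32. The cell cycle kinase gene CDK6 rose by 1.46 ± 0.13 (adjusted p = 1.17e-07) and MYC, a transcription factor that drives growth, by 0.54 ± 0.09 (adjusted p = 0.000731). In the list of feedback inhibitors, which shares 7 genes with the first, 6 of 22 rose, 1 fell and 15 did not pass, with 8 and 1 adjusted over the list alone (median log2 difference 0.09, camera, adjusted p = 0.000106). SOCS1 rose 2.63-fold (log2 difference 1.40 ± 0.17, adjusted p = 1.22e-05) and the phosphatase gene DUSP5 1.83-fold. The gene that fell in this list was DUSP10 (-0.45 ± 0.12, lower in 8 of 9 pairs, adjusted p = 0.0268), named after its value was seen.

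Most components of the receptor and its immediate signalling chain did not pass the test. IL2RA and the exchange factor gene SOS1 (1.04 ± 0.17, adjusted p = 0.000394) rose, PIK3R1, a regulatory subunit of PI3 kinase, fell by 0.39 in 8 of 9 pairs (adjusted p = 0.00572), and 11 of 14 components did not pass. Adjusted over the list alone 5 rose and 1 fell, and with the block 5 and 2. The list was shifted up (median log2 difference 0.11, camera, adjusted p = 0.00845, and adjusted p = 0.182 with an estimated correlation). That call was also lost after quantile normalization (adjusted p = 0.187), after cyclic loess (adjusted p = 0.278, and 0.115 with the block) and without the dimmest 40% of genes (adjusted p = 0.123). IL2RB, the beta chain of the receptor, differed by 0.54 ± 0.19 and was higher in all 9 pairs without passing the test (adjusted p = 0.109), and it passed with the block (adjusted p = 2.65e-05). IL2RG, the shared gamma chain, differed by 0.13 ± 0.11 (adjusted p = 0.519).

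**Figure D2:**
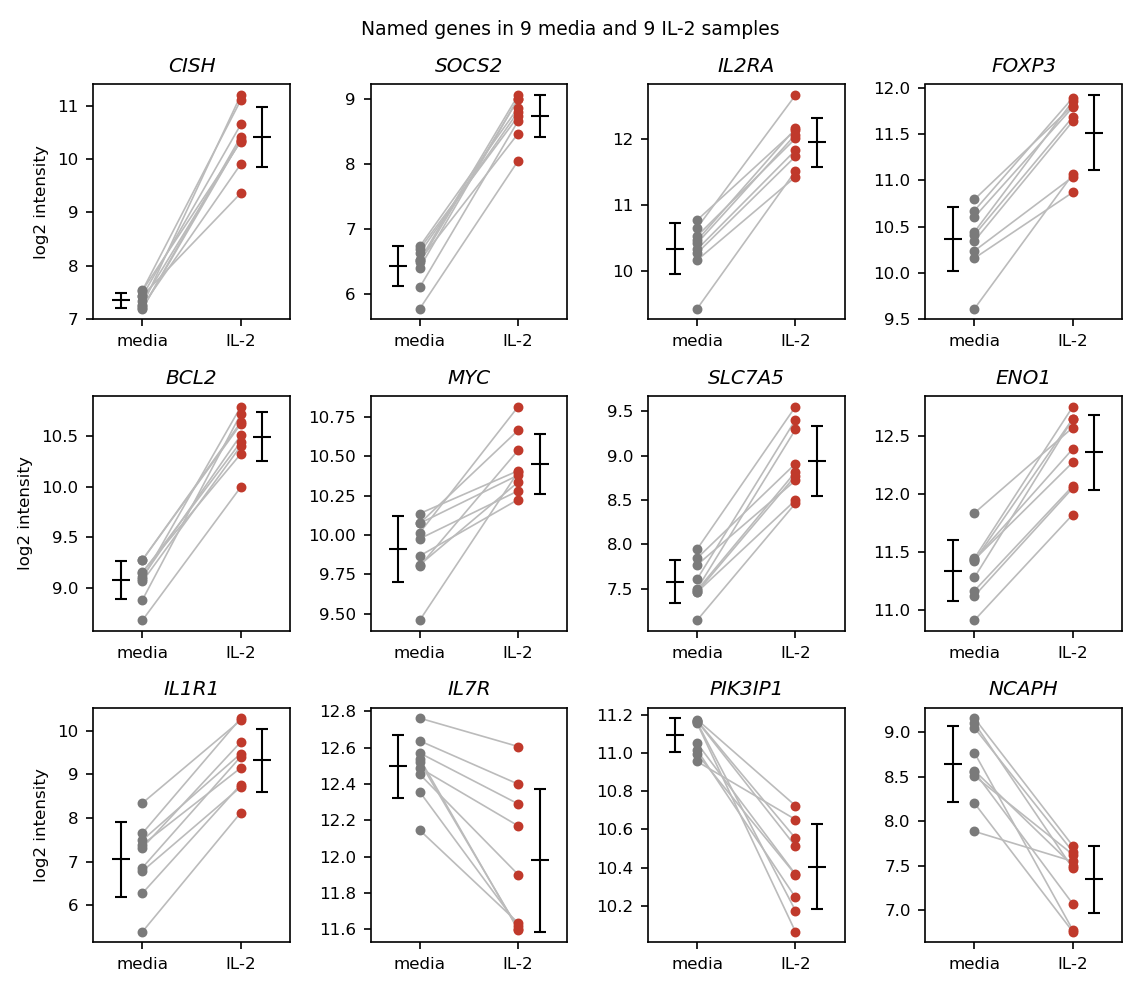
Log2 intensity (vertical axis, a separate range for each gene, not starting at 0) of 12 named genes in the 9 media samples (grey) and the 9 IL-2 samples (red), with lines joining same-numbered samples and bars for the mean ± SD of each group. In all 9 pairs CISH, SOCS2, IL2RA, FOXP3, BCL2, MYC, SLC7A5, ENO1 and IL1R1 were higher with IL-2, and IL7R, PIK3IP1 and NCAPH were lower.

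Transcripts that mark regulatory T cells were partly raised. FOXP3, the lineage-defining transcription factor, went from 10.36 ± 0.35 to 11.51 ± 0.40 (2.22-fold, adjusted p = 8.15e-05). HPGD, an enzyme that degrades prostaglandins, rose 2.93-fold (1.55 ± 0.23), the adhesion receptor gene LAYN 2.4-fold and IKZF4, which encodes the FOXP3 partner Eos, 2.36-fold. Of 40 measured signature genes, 9 rose, 1 fell and 30 did not pass. Of these genes 16 rose and 1 fell when adjusted over the list alone, and 19 and 2 with the block (median log2 difference 0.22, camera, adjusted p = 5.21e-07, and adjusted p = 0.177 with an estimated correlation). CTLA4, an inhibitory receptor, differed by 0.09 ± 0.15 (adjusted p = 0.741) and IKZF2, which encodes Helios, by 0.01 ± 0.11 (adjusted p = 0.982). TNFRSF18, which encodes GITR, differed by 0.44 ± 0.15, higher in 8 of 9 pairs (adjusted p = 0.0964), and passed with the block (adjusted p = 0.00377). The signature gene that fell was IL10, an anti-inflammatory cytokine (-0.47 ± 0.12, adjusted p = 0.0151).

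Among 21 measured suppressive effector molecules, LGALS1, which encodes galectin-1, rose by 0.62 ± 0.16 (adjusted p = 0.0189, and adjusted p up to 0.0654 without replicate 4), while IL10 and GZMA, a granzyme, fell, the latter by 0.62 (adjusted p = 0.000856), and 18 did not pass. IL10 (5.99 ± 0.32 in media) and GZMA (6.09 ± 0.18) both lay below the background level of 6.27. Adjusted over the list alone 5 rose and 2 fell, and with the block 9 rose and 2 fell. The list as a whole was not called (median log2 difference 0.14, camera, adjusted p = 0.126) and was called up with the block (adjusted p = 0.0337) and without the dimmest 40% of genes (adjusted p = 0.0474), but not with an estimated correlation (adjusted p = 0.429, and 0.252 with the block). GZMB, another granzyme, differed by 0.06 ± 0.08 (adjusted p = 0.683).

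Of the survival genes, 3 of the BCL2 family rose. BCL2 went from 9.08 ± 0.19 to 10.49 ± 0.24 (2.67-fold, adjusted p = 5.21e-09), BCL2L1 rose 1.87-fold (0.91 ± 0.15) and MCL1 1.44-fold (0.53 ± 0.08). These were the 3 of 9 measured anti-apoptotic genes that rose, and adjusted over the list alone 3 rose and 1 fell (median log2 difference 0.10, camera, adjusted p = 0.00166). Pro-apoptotic genes rose as well in 3 of 20 cases, with 4 adjusted over the list alone (median log2 difference 0.06, camera, adjusted p = 0.0244, and adjusted p = 0.245 with an estimated correlation). With the block 8 rose and 1 fell. Without replicate 9 the median was 0.04. They were CASP8 (0.38 ± 0.07, adjusted p = 0.0016) and CASP9 (0.58 ± 0.14), which encode caspases, and PMAIP1 (0.61 ± 0.14), which encodes NOXA. By the exact rank-sum test CASP9 and PMAIP1 did not pass (adjusted p = 0.0531 for both), nor did PMAIP1 without replicates 1 and 8 (adjusted p = 0.0541). The pro-apoptotic call was also lost after quantile normalization (adjusted p = 0.114), after cyclic loess (adjusted p = 0.106, and 0.0980 with the block) and without the dimmest 40% of genes (adjusted p = 0.114). Of 20 p53 target genes 1 rose, MDM2 (0.30 ± 0.08, adjusted p = 0.0253, and adjusted p up to 0.0677 without replicate 1, 4, 5, 7 or 9, and 0.112 at most over the alternatives). Adjusted over the list alone 2 rose and 1 fell, and with the block 6 and 3. That list was not called (median log2 difference 0.04, camera, adjusted p = 0.248). Its median was -0.01 after quantile normalization.

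Lists of biosynthesis genes were shifted up. Of 26 measured genes of amino acid transport and synthesis 15 rose and 11 did not pass, with 17 rising when adjusted over the list alone (median log2 difference 0.36, camera, adjusted p = 3.46e-18). The serine synthesis gene PSAT1 rose 2.82-fold (adjusted p = 5.12e-05), the amino acid transporter genes SLC7A5 and SLC1A5 2.56-fold and 2.51-fold, and MTHFD1L, a mitochondrial enzyme of folate metabolism, 2.44-fold (adjusted p = 3.56e-08). Among 29 genes of ribosome biogenesis and the nucleolus 15 rose and 14 did not pass. Adjusted over the list alone 20 rose, and with the block 26 (median log2 difference 0.33, camera, adjusted p = 1.57e-19). BYSL rose by 0.75 ± 0.11, DDX21 by 0.70 ± 0.11, RRS1 by 0.70 ± 0.15 and WDR12 by 0.69 ± 0.08. Cytosolic ribosomal proteins and elongation factors, in contrast, had 0 of 24 genes called by limma, 0 at an unadjusted p under 0.05 and 0 with the block (median log2 difference 0.03, camera, adjusted p = 0.229). Their median was -0.01 after quantile normalization and also just below 0 after cyclic loess.

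Nucleotide synthesis genes rose in 9 of 21 cases, with 12 adjusted over the list alone and 15 with the block (median log2 difference 0.24, camera, adjusted p = 1.30e-12). The purine synthesis gene PAICS rose 1.96-fold (0.97 ± 0.11, adjusted p = 6.15e-06), NME2, a nucleoside diphosphate kinase gene, 1.78-fold and CTPS1, which makes CTP, 1.53-fold. Of 19 cytosolic chaperone genes, 11 rose. The list had 17 rising and 1 falling when adjusted over the list alone and 17 and 1 with the block (median log2 difference 0.40, camera, adjusted p = 3.60e-15). STIP1 rose by 0.75 ± 0.11, HSPH1 by 0.66 ± 0.11 and CCT5, a subunit of the TRiC chaperonin, by 0.60 ± 0.10. Proteasome genes rose in 6 of 25 cases, with 14 adjusted over the list alone and 21 with the block (median log2 difference 0.28, camera, adjusted p = 5.38e-12, and adjusted p = 0.114 with an estimated correlation). Among those that rose were PSMD14 (0.59 ± 0.11), PSMB6 (0.51 ± 0.11) and PSMA3 (0.43 ± 0.09). In the endoplasmic reticulum list 1 gene rose, 1 fell and 21 of 23 did not pass. These counts were 2 and 1 adjusted over the list alone and 11 and 1 with the block (median log2 difference 0.15, camera, adjusted p = 0.000461, and adjusted p = 0.366 with an estimated correlation). EDEM1, which helps degrade misfolded proteins, was the gene that fell (-0.40 ± 0.09, adjusted p = 0.0115).

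Lists of energy metabolism were shifted up as well. ENO1, the glycolytic enolase, rose 2.03-fold (1.02 ± 0.13, adjusted p = 2.11e-05), the hexokinase gene HK2 by 0.54 ± 0.10, the glucose transporter gene SLC2A1 by 0.53 ± 0.08 and LDHA, lactate dehydrogenase A, by 0.51 ± 0.13 (adjusted p = 0.0185, and adjusted p up to 0.0599 without replicate 4 or 7, and 0.0673 at most over the alternatives). Of 20 glycolysis genes 7 rose. The count was 11 adjusted over the list alone and 12 with the block, where 1 fell (median log2 difference 0.30, camera, adjusted p = 2.82e-07, and adjusted p = 0.114 with an estimated correlation). Hypoxia-inducible genes, 3 of which are also glycolysis genes, rose in 6 of 17 cases, 8 adjusted over the list alone and 10 with the block, where 1 fell (median log2 difference 0.18, camera, adjusted p = 0.000461). Among them were PDK1 (0.51 ± 0.09) and NDRG1 (0.48 ± 0.07). Oxidative phosphorylation and citrate cycle genes rose in 3 of 28 cases. The number was 5 adjusted over the list alone and 16 with the block (median log2 difference 0.19, camera, adjusted p = 2.72e-07, and adjusted p = 0.119 with an estimated correlation). IDH3A rose by 0.39 ± 0.07. Among cholesterol genes 4 of 19 rose. This number was 7 adjusted over the list alone and 11 with the block (median log2 difference 0.18, camera, adjusted p = 0.000113, and adjusted p = 0.342 with an estimated correlation). STARD4, which carries cholesterol, rose by 0.88 ± 0.18 and IDI1 by 0.50 ± 0.11, and HMGCS1 differed by 0.12 ± 0.10 (adjusted p = 0.534). Fatty acid synthesis genes had 1 of 15 called, the desaturase SCD, whose mean lay below 6.27 in both groups (0.58 ± 0.14 in 8 of 9 pairs, adjusted p = 0.0157, and adjusted p up to 0.0594 without replicate 3, 4, 5 or 7, and 0.0673 at most over the alternatives). With the block 7 rose, and 3 adjusted over the list alone (median log2 difference 0.20, camera, adjusted p = 0.00134, and adjusted p = 0.177 with an estimated correlation). The call of the list was lost without the dimmest 40% of genes (adjusted p = 0.0617).

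**Figure D3:**
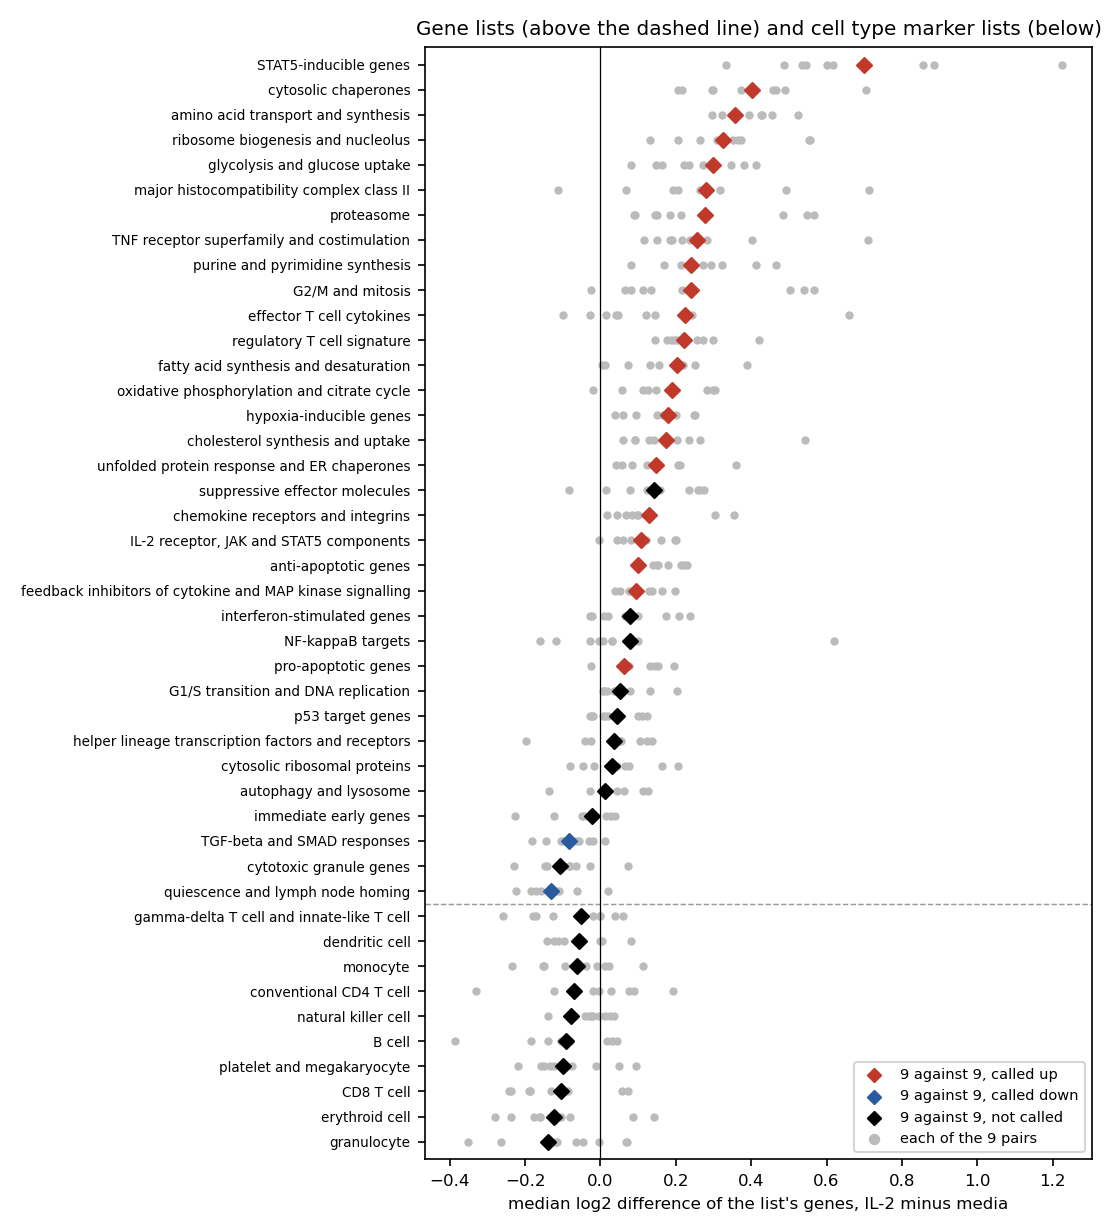
Median log2 difference (horizontal axis, IL-2 minus media) of the measured genes of each of the 34 gene lists and 10 cell type marker lists, as diamonds for 9 against 9 samples (red called up, blue called down, black not called by camera) and grey points for the 9 same-numbered pairs. The STAT5-inducible genes lie farthest right, with pair medians from 0.33 to 1.22, and none of the marker lists is called.

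Most cell cycle genes did not pass the test, and the median level of the G2/M genes was 6.05. Of 29 G2/M and mitosis genes 2 rose, 8 adjusted over the list alone and 14 with the block (median log2 difference 0.24, camera, adjusted p = 2.05e-06, and adjusted p = 0.262 with an estimated correlation). The call was lost without the dimmest 40% of genes (adjusted p = 0.233). The genes that rose were TOP2A (0.63 ± 0.16, adjusted p = 0.0238, and adjusted p up to 0.0735 without replicate 1, 2 or 3, and 0.0962 at most over the alternatives) and CCNA2 (0.38 ± 0.11, adjusted p = 0.0404, and adjusted p up to 0.125 without replicate 1, 2, 3, 4, 5, 6 or 7, and 0.149 at most over the alternatives). MKI67, which encodes the proliferation marker Ki-67, went from 5.59 ± 0.24 to 6.04 ± 0.50, higher in all 9 pairs (adjusted p = 0.12), and passed with the block (adjusted p = 0.00137). TOP2A (5.59 ± 0.27 in media and 6.22 ± 0.48 with IL-2) and MKI67 lay below 6.27 in both groups, the level of background given by olfactory receptor genes. G1/S and DNA replication genes had 0 of 33 called by limma, with 5 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone and 8 higher and 1 lower with the block. That list was not called (median log2 difference 0.05, camera, adjusted p = 0.0777), and it was called up with the block (adjusted p = 0.0375), after quantile normalization (adjusted p = 0.0473), after cyclic loess (adjusted p = 0.0458) and without replicate 6 (adjusted p = 0.0381). With an estimated correlation it was not called (adjusted p = 0.342, and 0.331 with the block).

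The list of quiescence and lymph node homing genes was shifted down, with 5 genes that fell. PIK3IP1, an inhibitor of PI3 kinase, went from 11.09 ± 0.09 to 10.41 ± 0.22 (1.61-fold lower, adjusted p = 9.47e-06), SESN3 fell by 0.56 and the transcription factor FOXP1 by 0.37. IL7R, the transcript of the CD127 used in the sort, differed by -0.52 ± 0.13 (adjusted p = 0.0197, and adjusted p up to 0.0712 without replicate 4, 7 or 9, and 0.1 at most over the alternatives). Of 27 measured genes 5 fell and 22 did not pass. Adjusted over the list alone 7 fell and 1 rose, and with the block 12 and 5 (median log2 difference -0.13, camera, adjusted p = 0.00199, and adjusted p = 0.342 with an estimated correlation). KLF2, a transcription factor of resting T cells, differed the other way by 0.18 ± 0.07 (adjusted p = 0.151) and passed with the block (adjusted p = 0.0115). TGF-beta and SMAD genes were the other list shifted down: 4 of 18 fell and 1 rose, and adjusted over the list alone 4 fell and 1 rose (median log2 difference -0.08, camera, adjusted p = 0.0345, and adjusted p = 0.182 with an estimated correlation). TGIF1 fell by 0.62, TGFBR2 by 0.50 and SMAD3 by 0.43, while TGFBR1, the other receptor chain, rose by 0.76 ± 0.13 (adjusted p = 0.000745). The TGF-beta call was lost with the block (adjusted p = 0.0514) and without replicate 3, 4 or 6 (adjusted p = 0.0702, 0.0515 and 0.0614). Its median was -0.05 without replicate 4 and -0.12 without replicates 1 and 8.

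The list of TNF receptor and costimulation genes was shifted up, with 5 genes that rose. CD80, a ligand of CTLA4 and CD28, rose 2.99-fold (1.58 ± 0.30, adjusted p = 0.0018), and the cytokine genes LTA and TNF rose 2.37-fold and 2.28-fold. IL-2 sample 9 stood apart in LTA (11.10 against 9.62 in the nearest sample) and in the median of this list (9.78 against 8.87). Without replicate 9, LTA was 0.97 and the list median 0.23, and both passed. Of 21 genes in that list 5 rose, or 11 adjusted over the list alone and 11 rising and 3 falling with the block (median log2 difference 0.26, camera, adjusted p = 0.000113, and adjusted p = 0.177 with an estimated correlation). LTA and TNF were also the 2 of 13 effector cytokine genes that rose. With the block 2 rose and 1 fell, and 2 rose adjusted over the list alone (median log2 difference 0.22, camera, adjusted p = 0.0359, and adjusted p = 0.342 with an estimated correlation). The effector cytokine call was lost with the block (adjusted p = 0.0608) and without replicate 4 or 9 (adjusted p = 0.0736 and 0.0715), where the median was 0.06 and 0.04. NF-kappaB targets went both ways, with TNF and NFKBIZ (0.59 ± 0.12) rising and TNFAIP3, an inhibitor of NF-kappaB, falling by 0.88 (adjusted p = 0.00851). Among 23 targets 2 rose and 1 fell, 3 and 2 adjusted over the list alone and 5 and 2 with the block. The list was not called (median log2 difference 0.08, camera, adjusted p = 0.272). Immediate early genes had 1 of 20 called, MYC, and likewise 1 adjusted over the list alone. With the block 3 rose and 2 fell (median log2 difference -0.02, camera, adjusted p = 0.941). The median and mean of this list were below 0 and its test statistic above 0.

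Homing receptors and lineage factors changed in a few members. ITGA4, the integrin alpha 4 chain, rose 2.24-fold (1.16 ± 0.12, adjusted p = 1.45e-06), the chemokine receptor gene CCR2 rose by 1.01 ± 0.26 (adjusted p = 0.0192, and adjusted p up to 0.0672 without replicate 7, and 0.1 at most over the alternatives), and CXCR6 differed by -0.58 ± 0.15, lower in 8 of 9 pairs (adjusted p = 0.0241, and adjusted p up to 0.0813 without replicate 4, 5, 6 or 7, and 0.166 at most over the alternatives). Of 23 chemokine receptors and integrins 3 rose and 1 fell. The counts were 5 and 2 adjusted over the list alone and 9 and 4 with the block (median log2 difference 0.13, camera, adjusted p = 0.0359, and adjusted p = 0.342 with an estimated correlation). That call was lost without replicate 1, 2 or 8 (adjusted p = 0.0660, 0.0661 and 0.0568), with array weights (adjusted p = 0.0888), after cyclic loess (adjusted p = 0.0928), without replicates 1 and 8 together (adjusted p = 0.108) and without the dimmest 40% of genes (adjusted p = 0.310). AHR (0.97 ± 0.13), IL4R (0.75 ± 0.17) and MAF (0.69 ± 0.11) were the 3 of 17 helper lineage genes that rose, IL4R not by the exact rank-sum test (adjusted p = 0.0531). The counts were 3 rising and 1 falling when adjusted over the list alone and 4 and 3 with the block (median log2 difference 0.03, camera, adjusted p = 0.234). The helper list's median was -0.01 after quantile normalization and after cyclic loess. Major histocompatibility complex class II genes had 0 of 8 called by limma and 3 higher at an unadjusted p under 0.05. In that list 0 passed adjusted over the list alone, and 5 rose with the block (median log2 difference 0.28, camera, adjusted p = 0.0331, and adjusted p = 0.429 with an estimated correlation). The list was not called without replicate 8 or 9 (adjusted p = 0.0527 and 0.0930) or without the dimmest 40% of genes (adjusted p = 0.129).

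Interferon-stimulated genes rose in 2 of 32 cases, with 2 adjusted over the list alone and 10 rising and 2 falling with the block. The list was not called (median log2 difference 0.08, camera, adjusted p = 0.143), and it was called up with the block (adjusted p = 0.00773) and without replicate 4 (adjusted p = 0.0495), but not with an estimated correlation (adjusted p = 0.768, and 0.37 with the block). Its median was 0.04 without replicate 4 and 0.05 without replicate 6 or 8. Its 2 called genes were GBP5 (1.04 ± 0.28, adjusted p = 0.0253, and adjusted p up to 0.0658 without replicate 1, 2, 3, 6, 7 or 8, and 0.15 at most over the alternatives) and IRF9 (0.65 ± 0.17, adjusted p = 0.0264, and adjusted p up to 0.0803 without replicate 1, 2, 3, 5, 6, 7, 8 or 9, and 0.0991 at most over the alternatives). GBP5 and IRF9 passed with the block (adjusted p = 7.97e-06 and 5.67e-07). In the autophagy and lysosome list 1 of 21 fell, NPC1, a lysosomal cholesterol transporter gene, by 0.41 in 8 of 9 pairs (adjusted p = 0.00867), with 1 adjusted over the list alone and 4 rising and 1 falling with the block (median log2 difference 0.01, camera, adjusted p = 0.552). The autophagy list's median was -0.03 after quantile normalization and -0.02 after cyclic loess.

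Among the remaining large changes, IL1R1, the receptor of interleukin-1, went from 7.06 ± 0.85 to 9.32 ± 0.72 (4.8-fold, adjusted p = 0.000105), and the prostaglandin E2 receptor gene PTGER2 rose 4.71-fold (2.24 ± 0.16). MB21D2 rose 4.22-fold, the kinase gene SGK1 3.92-fold, the quinone reductase gene NQO1 3.37-fold and TLR1, a Toll-like receptor gene, 3.34-fold (adjusted p = 1.37e-07). TLR6, a close relative of TLR1, fell by 0.91 (adjusted p = 0.0016). The IL-2 levels of TLR6 (5.66 ± 0.45) and AOAH (5.90 ± 0.62) lay below 6.27, the background level given by olfactory receptor genes, so the sizes of their differences are uncertain. The 10 largest falls among the genes that passed were, in order, in NCAPH, DPEP2, SPON1, AOAH, JAML, ADA2, PASK, TLR6, TIMD4 and SNED1. The largest after NCAPH was in the dipeptidase gene DPEP2 (2.09-fold lower, adjusted p = 1.31e-06). The adhesion gene JAML was 2-fold lower, the kinase gene PASK 1.92-fold, TIMD4 1.88-fold and SNED1 1.86-fold. SPON1 differed by -1.05 ± 0.27 (adjusted p = 0.024, and adjusted p up to 0.0816 without replicate 7 or 9, and 0.082 at most over the alternatives), ADA2, which encodes an adenosine deaminase, by -0.95 ± 0.25 (adjusted p = 0.0273, and adjusted p up to 0.0785 without replicate 3, 6, 8 or 9, and 0.0915 at most over the alternatives) and AOAH by -1.04 ± 0.31 (adjusted p = 0.0499, and adjusted p up to 0.141 without replicate 1, 2, 3, 4, 6, 7, 8 or 9). SPON1, ADA2 and AOAH passed with the block (adjusted p = 1.69e-06, 3.40e-06 and 9.46e-06).

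None of the 10 lists of markers of other blood cells was called by camera, and 1 of them (CD8 T cell) passed at an unadjusted p under 0.05. Median log2 differences were -0.09 for B cell (adjusted p = 0.304), -0.06 for monocyte (adjusted p = 0.774), -0.06 for dendritic cell (adjusted p = 0.233), -0.08 for natural killer cell (adjusted p = 0.941) and -0.05 for gamma-delta and innate-like T cell markers (adjusted p = 0.941). They were -0.10 for platelet (adjusted p = 0.229), -0.12 for erythroid (adjusted p = 0.113), -0.14 for granulocyte (adjusted p = 0.126) and -0.07 for conventional CD4 T cell markers (adjusted p = 0.843). Only the last (8.67) and the gamma-delta list (7.11) had median levels above 6.27, so the other lists say little about other cells. The 361 olfactory receptor genes had a median difference of -0.07. Among 10000 random lists matched on level the marker medians lay at percentile 4.86 to 69.26, the granulocyte median at 0.6. Single members rose: CD79B of the B cell list (0.56 ± 0.12, adjusted p = 0.00535), NCR3 of the natural killer list (0.67 ± 0.14, adjusted p = 0.0036), LYZ of the monocyte list (0.84 ± 0.24, 8 of 9 pairs, adjusted p = 0.0382) and KLRD1 of the natural killer list (0.71 ± 0.21, 7 of 9 pairs, adjusted p = 0.0484). They were named after their values were seen, and KLRD1 in both groups and LYZ in media (6.00 ± 0.55) lay below 6.27, so the sizes of their differences are uncertain. With the block 1 B cell, 1 monocyte and 2 natural killer markers were higher in limma. Lower were 1 B cell, 1 natural killer, 1 platelet, 1 erythroid, 2 dendritic cell and 3 granulocyte markers. The CD8 T cell markers had a median of -0.10 (adjusted p = 0.068) and were called down with the block (adjusted p = 0.0108), without replicate 3 (adjusted p = 0.0472) and without replicates 1 and 8 (adjusted p = 0.0402). With an estimated correlation they were not called (adjusted p = 0.342, and 0.122 with the block). KLRG1 (-0.92 ± 0.33, adjusted p = 0.116, and 5.68e-07 with the block) and GZMK (-0.49 ± 0.39, adjusted p = 0.512, and 0.0124 with the block) were the members that passed with the block, named after their values were seen. The marker list shares 3 genes with the cytotoxic granule list, in which GZMA fell and 13 of 14 genes did not pass. In that list 1 rose and 1 fell when adjusted over the list alone and 1 rose and 3 fell with the block (median log2 difference -0.11, camera, adjusted p = 0.248). The dendritic cell median was 0.01 after cyclic loess. The median of the natural killer and monocyte lists was below 0 and their mean above it, with a test statistic above 0 for the first and below 0 for the second (mean 0.04 and 0.03), as it was for conventional CD4 T cell markers (0.17, test statistic below 0). Of those, DPP4 (1.29 ± 0.15) and BHLHE40 (1.28 ± 0.36) rose while IL7R and PDE3B (-0.45 ± 0.08) fell. DPP4, BHLHE40 and PDE3B were named after their values were seen.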

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

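In each group of 9 samples, the named genes and the medians of the 44 lists were searched for a sample whose gap to its nearest neighbour took up an unusually large share of the group's whole range. Of 314 such groups 29 had one, and chance alone flags about 1 in 20 groups, or 15.7. The share of the range is given for each, and the rule of this search was set before the values were seen. Some tests under the other observations below were chosen afterwards, as said there.

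Media sample 5 had the lowest IKZF2 (share 0.558) and IL2RA (0.548, level 9.43 against 10.16 in the nearest sample), and the highest IL4R (0.504), conventional CD4 T cell marker median (0.53), amino acid list median (0.565) and effector cytokine median (0.494). Media sample 4 had the highest IRF9 (0.629), ITGB7 (0.511) and class II median (0.561), and the lowest MYC (0.507), platelet marker median (0.561) and hypoxia median (0.507). IL-2 sample 4 had the highest IRF9 as well (0.635), at 10.61 against 9.91 in the nearest sample. IRF9 was thus highest in number 4 of both groups.

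IL-2 sample 9 had the highest LTA (0.526, level 11.10 against 9.62 in the nearest sample) and LGALS1 (0.555), and the lowest PDK1 (0.522). It also had the highest median of the effector cytokines (0.717, 6.44 against 5.18), of the NF-kappaB targets (0.783, 9.36 against 7.97) and of the TNF receptor and costimulation list (0.575). Media sample 9 had the highest SOCS1 (0.53) and helper lineage median (0.554). IL-2 sample 8 had the lowest NDUFA9 (0.672), PSMA4 (0.589) and amino acid median (0.59), and media sample 8 the lowest IL2RG (0.596). Media sample 1 had the lowest glycolysis (0.496) and cholesterol medians (0.497), IL-2 sample 1 the lowest chemokine receptor and integrin median (0.536), and media sample 6 the highest SCD (0.508).

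Transcript clusters outside the comparison of genes held signal as well. Of 1680 with several gene symbols (those that name XIST, TSIX or a Y-linked gene were left out), 24 were higher and 7 lower with IL-2 at an adjusted p under 0.05 in limma, and of 12060 with no gene symbol 25 were higher and 3 lower. With the block the counts were 141 and 127 for the first kind and 184 and 101 for the second.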

How the results depend on the processing

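The alternatives with cyclic loess, and the one without replicates 1 and 8, were added after the data were seen. No called result changed direction in any alternative, while the medians of 5 lists that were not called changed sign under another scaling. With the replicate number as a block, 2464 genes were higher and 1568 lower, as a random block 2385 and 1726, and with the block after cyclic loess 2065 and 1517, with 69 at least 1.5-fold lower. These fits take the spread between same-numbered pairs out of the error. A second quantile normalization gave 407 lower genes and cyclic loess 367; the cause was not tested. An adjusted p under 0.01 left 439 higher and 89 lower genes and 25 at least 1.5-fold lower, by its own construction, and the exact rank-sum test gave 24 of the last kind; the cause was not tested. Leaving out 1 replicate number at a time, which leaves fewer samples, gave 122 to 213 lower genes (153, 122 and 152 without replicates 4, 7 and 9) and 1 to 2 lists down (1 without replicate 4 or 6), while higher genes ran from 557 to 734, genes at least 1.5-fold higher from 201 to 250, genes at least 1.5-fold lower from 29 to 53 and lists up from 20 to 23. With a correlation estimated per list, 8 lists were up and 0 down by camera, and 0 down at an unadjusted p under 0.05; with the block as well, 2 lists passed, the amino acid list and the regulatory T cell signature (adjusted p = 0.0421 and 0.0421). Of 104 called named genes, 78 kept their call in every alternative that was run on them and 26 lost it in at least 1, 23 of them when 1 replicate was left out and 22 by the exact rank-sum test (adjusted p up to 0.166, for CXCR6). All 26 passed with the block. The block changed no call of a named gene or list other than those printed with it. The signal over background limits dim genes: 361 olfactory receptor genes had a median level of 4.84 and a 95th percentile of 6.27, and 2 of them were called.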

Other observations

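The 5 gene lists added here (tRNA synthetases, NRF2 targets, interleukin-1 receptors, Toll-like receptors and condensin subunits) were written after the calls had been seen, without the genes that prompted them, and tested with limma's camera, adjusted over the 5. Members are named after their values were seen. The tests of the biosynthesis pattern, of TLR1 with TLR6 and of dividing cells were also chosen after the values they measure were seen, and the last of these replaced a first one. Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, rose in 12 of 19 cases (18 with the block, median log2 difference 0.42, adjusted p = 2.24e-17, and adjusted p = 0.00488 with an estimated correlation). WARS1 rose by 1.05 ± 0.19, YARS1 by 0.91 ± 0.14 and TARS1 by 0.87 ± 0.18. This is consistent with the hypothesis that they move with the amino acid list, with which they share 0 genes. Of 14 targets of NRF2, the transcription factor of the oxidative stress response, 9 rose (13 with the block, median 0.47, adjusted p = 2.81e-12, and adjusted p = 0.00488 with an estimated correlation). GCLM rose by 0.72 ± 0.16, TXNRD1 by 0.69 ± 0.13, PRDX1 by 0.59 ± 0.10 and GSR by 0.53 ± 0.10, beside TXN (1.69 ± 0.13) and NQO1 (1.75 ± 0.22), so NRF2 targets may rise as a group. The media level of GCLM (6.12 ± 0.38) lay below 6.27, so the size of its difference is uncertain. NRF2 activity was not measured, and 2 of the list's genes are also in the lists above, where their values had been seen.

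The other members of the interleukin-1 receptor family were not called as a group beside IL1R1 (median 0.14, 1 of 9 rose, adjusted p = 0.0852, and adjusted p = 0.349 with an estimated correlation). The list passed with the block at the preset correlation (adjusted p = 0.0434). The values of 3 of its genes had been seen in other lists. IL1R2, the decoy receptor, was the member that rose (0.70 ± 0.21, adjusted p = 0.0496). Toll-like receptors other than TLR1 and TLR6 had 0 of 6 called with and without the block (median 0.01, adjusted p = 0.928). All of them but TLR9 (7.32 in media) had mean levels below 6.27 in both groups, so a change could be missed. A p over the threshold was written down beforehand as the outcome against both ideas. In lists of 9 and 6 genes it does not show that a list did not move, so both stay open.

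The amino acid, ribosome biogenesis, nucleotide synthesis, chaperone and proteasome lists were shifted up, the last with 6 of 25 genes called and adjusted p = 0.114 with an estimated correlation. A shift between arrays that depends on intensity may add to this, since of 10 equal groups of genes by level the brightest 4 had median differences of 0.03 to 0.07 and the others of -0.03 to -0.09. The tables argue against it as the whole cause: each median lay at percentile 100 (rounded) of 10000 random lists matched on level, and after cyclic loess all 5 were still called, with medians of 0.21 to 0.37. Of the other lists called up, the medians of the IL-2 receptor component, anti-apoptotic and pro-apoptotic lists lay at percentiles 85.84, 86.05 and 81.79 of such random lists. For the medians of these lists a shift that depends on intensity thus stays open. Medians above 0 in 9 of 9 pairs for each of the 5 biosynthesis lists restate the pattern. They cannot tell a response to IL-2 from other differences between the cultures, such as the survival of cells without IL-2. Both stay open.

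TLR1 and TLR6 are neighbouring and related genes, and they moved in opposite directions, TLR1 by 1.74 ± 0.15 and TLR6 by -0.91 ± 0.17, each in 9 of 9 pairs. Signal shared between them, which was not checked on sequence, would move both the same way, so the TLR6 difference of -0.91, the observation itself, argues against it as the cause of opposite directions. Sharing that shrinks either difference stays open, and the TLR6 level with IL-2 (5.66 ± 0.45) lay below 6.27, so the size of its fall is uncertain. A candidate explanation is separate control of the 2 genes by IL-2, which was not tested.

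NCAPH fell by 1.30, in 9 of 9 pairs. Fewer dividing cells would lower other cell cycle genes; a first test on the G2/M list gave a median of 0.24, but that list lies near background, so after that value was seen it was replaced. The second test took the 34 of 62 G1/S and G2/M genes brighter than 6.27, whose median was 0.078 and lowest difference -0.22. NCAPH was picked as the largest fall, so lying below the genes nearest in level could not count against a shift that depends on intensity. The central 95% of the 500 nearest genes ran from -0.25 to 0.47. A shift shared by genes of that level would thus be smaller than the fall of NCAPH. The other 7 condensin subunits had a median of 0.10, and 0 of them were called lower in limma with or without the block. That argues against a fall of all subunits together, though NCAPG (5.99 in media and 6.24 with IL-2) lay below 6.27. The probes of NCAPH may also read another transcript that fell, which could explain the fall of NCAPH. That stays open because probe sequences were not used here.

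Chance was tested with 100 splits of the 18 samples into 9 and 9, the real one included, taking the larger direction of each other split. As many genes as the 813 higher came up in 2 splits (highest other 2320), and as the 235 lower in 3 (highest other 2320). As many as the 249 at least 1.5-fold higher came up in 1 split (highest other 195). For the 41 at least 1.5-fold lower it was 4 splits (highest other 195). These splits ignore the same-numbered pairs, and 4 of 100 lies close to 5%. The 2 counts at 1.5-fold were not counted separately in splits that part all pairs. Genes at 1.5-fold are a part of the called genes, and the highest other such split had 0 called genes without the block. That argues against chance for the 249 and the 41 genes too. As many lists as the 22 up came up in 4 of these splits (highest other 26), and as the 2 down in 92 (highest other 26). The split with 2320 genes points to a structure of the samples: it parted 3 of the 9 same-numbered pairs, where the real split parts 9 and the other splits parted a median of 5. Among 100 splits that part all 9 pairs, 1 gave as many higher and 1 as many lower genes, the real one in both cases. Chance is thus excluded at 5% for the 813 higher and the 235 lower genes. The highest other had 0 genes by limma without the block (1881 at an unadjusted p under 0.05, against 3439 in the real split) and 11 with the block. For lists, 5 of these splits gave as many as the 22 up and 89 as many as the 2 down (highest other 26 for both), so with the pairing kept and no block chance is not excluded at 5% for either count. With the block, 3 and 88 splits gave as many as its 24 up and 2 down (highest other 27). For lists up the answer thus depends on the fit, and for lists down chance is not excluded in any.

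Each pair's response was set against genes called without it, a comparison chosen after the calls were seen. Over the 679 to 925 genes called from the other 8 pairs, 91.9% to 99.1% had the same sign in the pair left out. The slope of its differences on those of the other pairs was 1.22 in pair 9, 1.16 in pair 4 and 1.15 in pair 7, and 0.664 to 0.992 in the others. Across genes, which are not independent replicates, the correlation was 0.804 to 0.940.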
